A study of Rattus norvegicus with 12 samples.

How the data were processed

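Gene expression was measured with Illumina rat bead arrays in fascicles of rat tail tendon, the fine collagen bundles in which tenocytes lie between fibres. Per the labels, fascicles were held in vitro under cyclic tensile strain or left unstrained for 1 h or 24 h, with 3 RNA samples in each of the 4 groups and 1 array per sample. Total RNA was extracted with Trizol, cleaned on columns with DNase treatment and labelled with biotin, per the labels' protocols. The labels do not say whether the 3 samples of a group came from separate animals or cultures, so p-values measure only the spread between these samples, which may be technical.

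The values used were the authors' deposited processed table, which holds 1 linear intensity per probe and array for 22517 probes on 12 arrays. The deposited intensity values were already normalized between arrays: every array has a median of 57.0, and the sorted values of any array differ from those of the first by at most 0.0928%, as quantile normalization leaves them. Whether a background was subtracted is not given in the sources used here, and the lowest value on each array was 33.7, so a background level remains in the values. The software and version behind this table are not given in the sources used here. A second deposited table with signals and detection p-values names its columns only by number, so none of its 24 columns of per-sample values could be tied to a sample, and none was used.

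No further background correction or normalization was applied, and the intensities were taken on the log2 scale. The remaining background makes fold changes of dim probes smaller than the change of the transcript. The design fixed before the files were opened assumed a table with detection p-values. None were used here, and probes were kept by the rule set for that case: the upper 50% by mean log2 signal over all 12 arrays, which left 11258 probes, the dimmest with a mean signal of 56.2. For arrays, the number of arrays limits the precision: the median standard error of a log2 fold change between 3 and 3 arrays was 0.12.

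Gene names came from GEO's platform annotation, in which 13787 of the 22517 probes have 1 gene symbol, 0 have several and 8730 are unnamed here. Symbols were compared with the current rat gene table (assembly GRCr8) through the Entrez identifier, which changed 0 of them. Among the kept probes, 7937 had a gene, for 7780 genes. For lists and named genes with several kept probes, the probe with the highest mean over all arrays was used. Of the genes named in the text, Axl, Tpm3 and Pi16 have a further kept probe. The 2 Axl probes were alike, with log2 fold changes of 0.45 and 0.46 for strain at 24 h. Those of Tpm3 differed, with 0.46 for the probe used and 0.16 for the other. For Pi16 at 1 h the values were -1.77 for the probe used and -0.70 for the other. Genomic positions are left out because no source used here gives the build of the array's annotation.

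Tests used limma 3.58.1 in R 4.3.3 (lmFit, contrasts.fit and eBayes), two-sided, with a mean per group over all 12 arrays, 8 residual and 4.08 prior degrees of freedom. There were 4 contrasts: strain at 1 h, strain at 24 h, the difference of these effects, and 24 h against 1 h in unstrained fascicles, which is the background change in the controls. A probe was called at a Benjamini-Hochberg adjusted p under 0.05 over all kept probes. Errors are standard errors of the fit unless given as SD. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.

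Before the data were examined, 34 lists of genes were fixed, of pathways, matrix components and markers of other cell types that a fascicle preparation could hold. Of 1033 list symbols, 1023 matched a gene, 825 genes were on the array and 643 were kept. Each list was compared with all other genes by camera with a preset correlation of 0.01, adjusted over the 34 lists of a contrast, and again with an estimated correlation. The fry test asked whether a list's genes moved, on balance, one way. With an estimated correlation and no block, 1 list call held, that of the matrix proteinases at 24 h of strain. By fry without a block, 7 list calls at 24 h of strain held and 4 were lost. All 15 for time held, and all 6 at 1 h and all 10 for the difference were lost.

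The genes named were also fixed by rule. For each strain contrast they were the 10 largest rises and 10 largest falls among called, named probes whose 3 strained arrays all lay on one side of the 3 unstrained arrays. With fewer than 5 in a direction, the genes of smallest p up to 5 were added and said not to pass. Up to 4 members of smallest p were taken from each list described. A fixed set of 14 genes was reported at both times: Col1a1, Col3a1, Dcn, Mmp3, Mmp13, Mmp14, Timp1, Timp3, Il6, Ptgs2, Scx, Tnmd, Egr1 and Fos. Scx has 0 probes among the named probes. For the difference and for time, the 5 largest in each direction were named. Other genes named were chosen after their values were seen, and are marked so or stand as members of a list.

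Replicate numbers 1 to 3 recur in the 4 groups, and the labels do not say what a number shares. Deviations from the group means were therefore correlated between the strained and unstrained array of each number. At 1 h the correlations were 0.604, 0.537 and 0.521, all over the limit of 0.1 set in advance, so the numbers were taken to pair the samples at 1 h. At 24 h that of replicate 1 was 0.0387, so the numbers were not taken as pairs for the main results there. The fit with the replicate number as a block within each time still blocked the arrays of both times. Its p-values at 1 h thus rest partly on the spread within 24 h pairs that the rule did not accept. The residual degrees of freedom given above are those of the fit without a block.

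The analysis was tested on simulated data with the real means of the 11258 probes and 200 changed probes. The spread of each probe was limma's fitted value, the same in all 4 groups. For strain at 1 h it recovered 62.7% of the probes changed 1.5-fold, 100% of those changed 2-fold and 100% of those changed 3-fold, with 7 false calls among 182. For strain at 24 h it recovered 68.7%, 98.5% and 98.5%. The replicate block was tested on separate simulated data, in which the 2 arrays of a pair were given shared noise. There it recovered 91.0% of the probes changed 1.5-fold at 1 h, with 13 false calls among 207. The fit without a block was not run on those data, so these shares cannot be compared. Noise was drawn independently for each probe, which real arrays do not follow. The recovered shares also depend on how many probes change. In the real data at 1 h without a block, Fos was 3.42-fold higher with a limma adjusted p of 0.537. Klf2 was 2.22-fold higher with one of 0.943. A probe not called at 1 h may thus have changed 2-fold or more.

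Alternatives tried were cyclic loess, no filter on dim probes, a stricter filter, a variance trend with robust estimation, array weights, fits on only the groups compared, the replicate number as a block, each array left out in turn, a minimum of 2-fold, and normexp background correction, the last chosen after seeing the data.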

Results

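The 12 arrays held 3 samples each of unstrained and strained rat tail tendon fascicles at 1 h and at 24 h, to ask how tenocytes in their own matrix change gene expression under cyclic tensile strain. Arrays of the same group correlated at 0.969 to 0.985 over all probes, and arrays of different times at 0.922 to 0.960. The highest correlations were between strained and unstrained arrays of 1 number at 1 h, 0.9863 for replicate 2 and 0.9857 for replicate 1. The first principal component held 53.8% of the variance and parted the 2 time points.

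After 1 h of strain, immediate early genes, which cells switch on first after a stimulus, stood higher in strained fascicles. Of 30 measured, 28 had a positive difference, and the median log2 fold change of the list was 0.53 (camera adjusted p = 1.94e-19; adjusted p = 0.114 with an estimated correlation). Fos, a subunit of the transcription factor AP-1, had a mean intensity of 328 ± 186 (SD, n = 3) in unstrained and 1140 ± 627 (SD, n = 3) in strained fascicles. Its log2 fold change was 1.77 ± 0.39. Atf3, a stress-induced transcription factor, doubled from 120 ± 22.6 to 260 ± 48.8 (SD, n = 3 each), a log2 fold change of 1.12 ± 0.15.

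Arrays of the same replicate number shared much of their spread at 1 h, and the outcome turned on it. Without the replicate block, limma called 0 of 11258 probes. The smallest adjusted p was 0.0768, that of Atf3, and 552 probes had an unadjusted p under 0.05, which is 4.90% of those tested. With a variance trend and robust estimation limma called 1 probe, Atf3, and with the replicate number as a block over all 12 arrays it called 0. With the replicate number as a block within each time, limma called 23 probes, 13 higher and 10 lower, with the same sign in all 3 pairs. That fit also blocked the 24 h arrays, whose numbers were not accepted as pairs, so its p-values rest partly on them.

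Among the 13 that rose with the block were 6 immediate early genes. Fos had an adjusted p of 1.63e-04, Atf3 of 0.0118, and Jun, the partner of Fos in AP-1, of 0.0132 at a log2 fold change of 0.86 ± 0.11. Klf2, a transcription factor induced by flow in endothelium, rose by 1.15, Klf4 by 0.61, and Dusp1, a phosphatase that shuts off MAP kinases, by 0.75. Hbegf, a ligand of the EGF receptor, rose by 1.11 and Rcan1, an inhibitor of calcineurin, by 1.00. Those that fell with the block included Pi16, at a log2 fold change of -1.77 ± 0.29, Aspn, the small leucine-rich proteoglycan asporin, at -0.86, Id1, a target of BMP signalling, at -0.78, Txnip at -0.88 and C1qa, a macrophage complement gene, at -0.85. Rcan1, Hbegf, Pi16, Aspn, Id1 and Txnip were chosen after their values were seen.

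**Figure D1:**
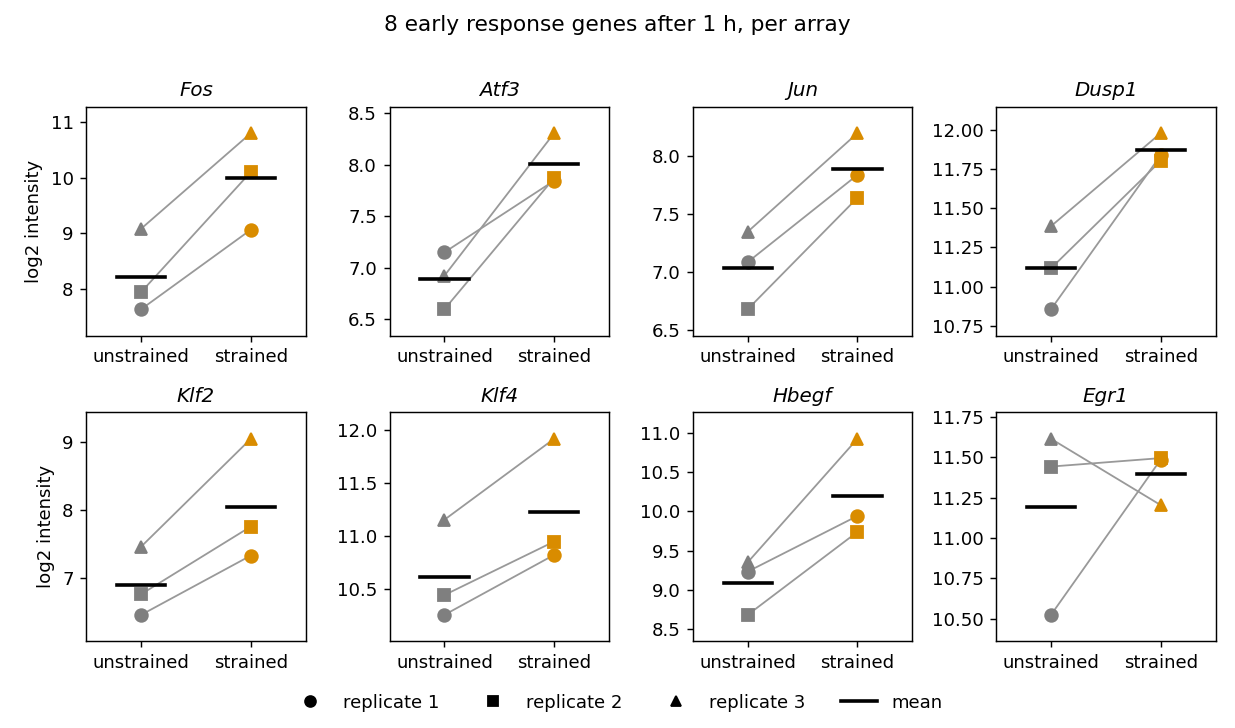
Log2 intensity of 8 early response genes after 1 h in unstrained (grey) and strained (orange) fascicles, each panel with its own axis. Points are arrays, lines join arrays of the same replicate number, and bars are means of 3. All genes but Egr1 stand higher in the strained array of every pair.

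Adjusted over the list alone and without the block, 10 of the 30 immediate early genes were higher, and none was lower. Dusp1 and Maff were among them, at 0.75 ± 0.14 and 0.53 ± 0.11. The list's adjusted p was 0.0856 by fry, and with the block 0.152 with an estimated correlation and 0.0426 by fry. Egr1, another early gene, was already bright in unstrained fascicles at 2464 ± 876 (SD, n = 3) and differed by 0.20 ± 0.41.

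Macrophage and leucocyte markers lay lower in strained fascicles at the same time, in 17 of 21 genes, at a median of -0.24 (camera adjusted p = 9.98e-04; adjusted p = 0.763 with an estimated correlation). C1qa, C1qc, C1qb and Tyrobp had log2 fold changes of -0.85, -0.62, -0.49 and -0.42, none past the test without the block. The list's call rested on 2 arrays: without strained replicate 3 its adjusted p was 0.319 at a median of -0.05, and without unstrained replicate 1 it was 0.785 at -0.04.

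Smaller shifts passed camera in 4 further lists at 1 h, with no member past the test. Heat shock proteins had a median of 0.10, led by Dnajb4 (0.36), Dnajb1 (0.25), Dnajb9 (0.57) and Hspa2 (0.24). Actin cytoskeleton genes and targets of SRF or YAP had a median of 0.14, led by Srf (0.55), Tpm4 (0.46), Cald1 (0.31) and Actn1 (0.43). Genes of the unfolded protein response had a median of 0.10, led by Dnajb11 (0.24), Pdia4 (0.37), Creld2 (0.36) and Herpud1 (0.29). Oxidative phosphorylation had a median of -0.07, led by Ndufs7 (-0.21), Sdhc (-0.19), Ndufb5 (-0.16) and Ndufa1 (-0.21). All 4 had a camera adjusted p of 0.0369, and adjusted p = 0.746 to 0.766 with an estimated correlation. All 4 also lost their call with array weights (0.0572 to 0.0659). Each lost its call without strained replicate 1 (adjusted p = 0.0725 to 0.647), strained replicate 3 (0.0792 to 0.319), unstrained replicate 2 (0.139 to 0.433) or unstrained replicate 3 (0.0706 or more). Glucocorticoid and circadian genes passed only with the block, at an adjusted p of 0.0394 against 0.0726 without it, with 1 member called, and adjusted p = 0.564 with an estimated correlation.

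Other genes of smallest p at 1 h did not pass: Arih1 at 0.49 and Nfkbiz at 0.55 among those higher, and Tppp3 at -0.61, Lpl at -0.95, Fbxl20 at -0.60, Gas7 at -0.69 and Pdlim1 at -0.53 among those lower. Tppp3 and Gas7 passed with the block. Of the matrix genes fixed in advance, Col1a1 had a log2 fold change of 0.33 ± 0.84, Col3a1 of -0.15 ± 0.71, Dcn (decorin) of 0.08 ± 0.09 and Tnmd (tenomodulin) of 0.16 ± 0.33. The proteinases Mmp3, Mmp13 and Mmp14 had values of 0.35, -0.04 and 0.10, and the inhibitors Timp1 and Timp3 of 0.32 and 0.22. Il6 stood at 0.89 ± 0.67 and Ptgs2, the inducible cyclooxygenase, at 0.85 ± 0.29. None of them passed with or without the block.

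After 24 h of strain, the largest differences were falls, and some complement and matrix proteinase genes were among the genes that fell, 4 of 21 and 6 of 26 measured. Orm1, an acute-phase glycoprotein, had a mean intensity of 1031 ± 248 in unstrained and 95.1 ± 10.1 in strained fascicles (SD, n = 3 each), 10.7-fold lower, with a log2 fold change of -3.42 ± 0.15 (limma adjusted p = 2.33e-07). Hp (haptoglobin) fell by 2.96 ± 0.13 on the log2 scale and Lbp, which binds bacterial lipopolysaccharide, by 3.00 ± 0.42. Among the genes that rose were Hbegf, 2.96-fold higher, and Tnfrsf12a, the receptor of TWEAK, 2.71-fold higher.

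In all, limma called 263 probes at 24 h, 109 higher and 154 lower, for 217 named genes. All 263 had their 3 strained arrays on one side of the 3 unstrained arrays, as had 20.5% of all kept probes, where chance gives 10%. At least a 2-fold change was reached by 13 of those that rose and 60 of those that fell.

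The 10 largest rises were those of Adgrg1, an adhesion receptor (1.63 ± 0.36), Hbegf (1.57 ± 0.29), Tnfrsf12a (1.44 ± 0.25), Esm1, a secreted proteoglycan (1.40 ± 0.22), Myadm (1.38 ± 0.31), Ncl (nucleolin, 1.21 ± 0.18), Pmepa1, a target of TGF-beta (1.18 ± 0.16), Ercc1, a DNA repair nuclease subunit (1.14 ± 0.25), Il1rl1, the interleukin 33 receptor (1.12 ± 0.25), and Sdc1 (syndecan 1, 1.07 ± 0.17). Their adjusted p ranged from 0.00396 for Pmepa1 to 0.0422 for Il1rl1. After Orm1, Lbp and Hp, the largest falls were those of Cyp4b1, a cytochrome P450 (-2.39 ± 0.14), Serping1, the inhibitor of complement C1 (-2.31 ± 0.36), Cd302 (-2.21 ± 0.36), Enpp2, which makes lysophosphatidic acid (-2.03 ± 0.23), Rgs2, a regulator of G protein signalling (-1.93 ± 0.46), Hsd11b1, which regenerates active glucocorticoid (-1.88 ± 0.40), and the MHC class I gene RT1-S3 (-1.86 ± 0.40). Rgs2 had the largest adjusted p of these, 0.0495.

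Complement and interferon response genes lay lower as a group: 21 of 21 had a negative value, with a median of -0.57. The 4 that fell were Serping1, C1s (-1.55 ± 0.31), C2 (-1.23 ± 0.27) and C1r (-0.80 ± 0.17), and 9 were lower adjusted over the list alone (camera adjusted p = 3.95e-09; adjusted p = 0.138 with an estimated correlation). Macrophage and leucocyte markers lay lower beside them, 18 of 21 negative at a median of -0.29, with Fcgr2b (-0.79 ± 0.13) and Cd53 (-0.63 ± 0.13) past the test and 5 lower adjusted over the list alone. S100a8 (-0.68 ± 0.19) and Fcer1g (-1.07 ± 0.32) did not pass. The camera adjusted p of the markers was 2.51e-05, and adjusted p = 0.514 with an estimated correlation.

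Matrix proteinases lay lower than other genes as a list, and without a block the list kept its call with an estimated correlation (camera adjusted p = 7.98e-06; adjusted p = 0.0401 with an estimated correlation). With the replicate block within each time, the call with an estimated correlation was lost. Of 26 measured, 6 fell and none rose, with 8 lower adjusted over the list alone, at a median of -0.12. The aggrecanase Adamts5 dropped from 546 ± 81.3 to 150 ± 8.25 (SD, n = 3 each), a log2 fold change of -1.86 ± 0.20. Adamts1 fell by 1.76 ± 0.26, the collagenase Mmp13 by 1.22 ± 0.16, the membrane-bound Mmp14 by 1.41 ± 0.25 and cathepsin B (Ctsb) by 1.00 ± 0.17, and Mmp9, chosen after its value was seen, stood at -0.65 (adjusted p = 0.0446) and lost its call in fits that left out an array, with an adjusted p up to 0.154 without unstrained replicate 2 at 24 h.

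**Figure D2:**
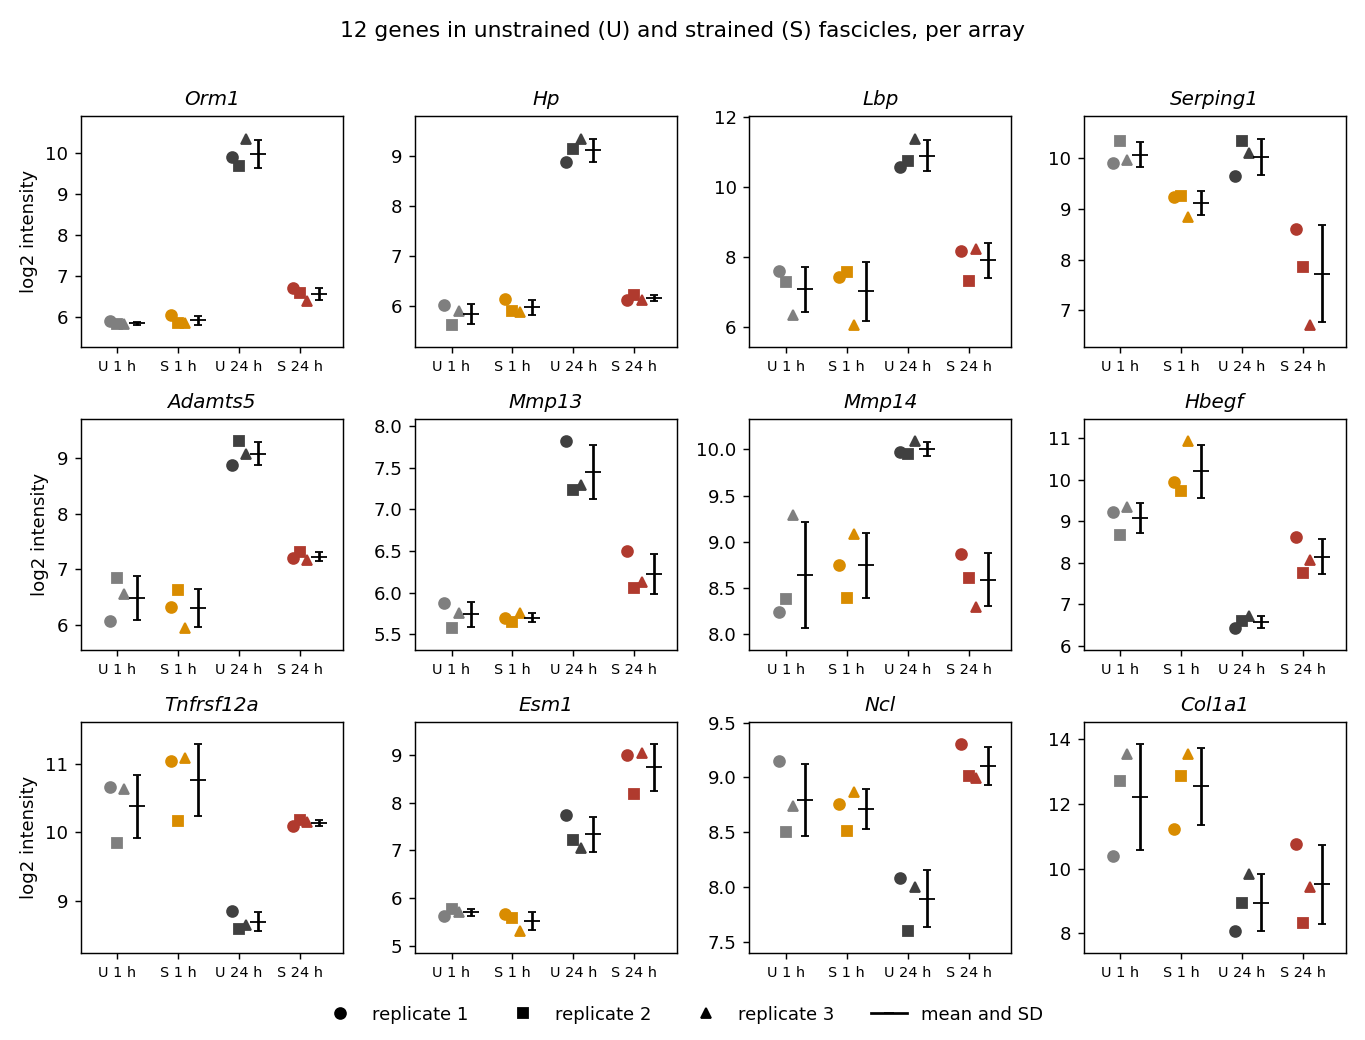
Log2 intensity of 12 genes in unstrained (U) and strained (S) fascicles at 1 h and 24 h, each panel with its own axis. Points are arrays, with the mean and SD of 3 beside them. Orm1, Hp, Lbp, Adamts5, Mmp13 and Mmp14 are highest in unstrained fascicles at 24 h, and the strained arrays at 24 h lie below those.

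Actin cytoskeleton genes and targets of SRF or YAP stood higher at 24 h, 20 of 23 with a positive value and a median of 0.39 (camera adjusted p = 8.33e-06; adjusted p = 0.138 with an estimated correlation). Ezr, the membrane linker ezrin, rose by 0.67 ± 0.12 and Fhl2 by 0.99 ± 0.21, and 7 were higher adjusted over the list alone. Tpm3 (0.46 ± 0.12) and Axl (0.45 ± 0.12) did not pass over all probes. Ribosomal protein genes had 45 of 48 positive values at a median of 0.15 (camera adjusted p = 8.67e-06; adjusted p = 0.145 with an estimated correlation). Rpl5 rose by 0.62 ± 0.15, 2 were higher adjusted over the list alone, and Rpl13, Rpl6 and Rps15 stood at 0.48, 0.33 and 0.38. Of 19 heat shock genes, Hspe1 rose by 0.76 ± 0.15, while Hspb1, Stip1 and Hspd1 stood at 0.51, 0.67 and 0.36. The median was 0.15, 2 were higher adjusted over the list alone, and camera gave an adjusted p of 0.00368 and adjusted p = 0.229 with an estimated correlation.

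Of 24 oxidative stress and metal response genes, 3 fell and none rose, both with all probes and adjusted over the list alone. They were the metallothioneins Mt1 (-1.55 ± 0.30) and Mt3 (-0.74 ± 0.15) and glutathione peroxidase 3 (Gpx3, -1.38 ± 0.32), and Ftl1 stood at -0.71. Cholesterol synthesis genes had 15 of 17 negative values at a median of -0.19, with Ebp (-0.54), Fdft1 (-0.39), Tm7sf2 (-0.57) and Insig2 (-0.44) not past the test. Cell cycle genes had 21 of 22 positive values at a median of 0.25, with none past the test over all probes and 1 adjusted over the list alone. Ccnd1 (cyclin D1) stood at 1.54 ± 0.37 (adjusted p = 0.0506), Mcm6 at 0.98, Mcm2 at 0.66 and Cdk4 at 0.43. Camera gave adjusted p of 0.00214 for oxidative stress, 7.19e-04 for cholesterol synthesis and 4.87e-04 for the cell cycle, and adjusted p = 0.424, 0.514 and 0.660 with an estimated correlation. The oxidative stress call was lost without strained replicate 3 at 24 h (adjusted p = 0.0570), as was that of the cell cycle (0.557, median 0.00), and that of cholesterol synthesis was lost without strained replicate 1 (0.0901).

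Markers of 2 further cell types passed camera at 24 h. The 5 smooth muscle and pericyte markers had a median of 0.33, with Cspg4 past the test at 0.81 ± 0.15, 3 higher adjusted over the list alone, and Des, Smtn and Synpo2 at 0.33, 0.51 and 0.07 (camera adjusted p = 0.0228; adjusted p = 0.248 with an estimated correlation). Cspg4 is also in the list of proteoglycans and matrix glycoproteins, so its rise is not a result of cell markers alone. The 7 nerve and Schwann cell markers had a median of -0.20, with Cnp past the test at -0.90 ± 0.21, also adjusted over the list alone, and Nefm, S100b and Mbp at -0.20, -0.32 and -0.12 (camera adjusted p = 0.0416; adjusted p = 0.229 with an estimated correlation). Both calls were lost without unstrained replicate 2 at 24 h (adjusted p = 0.0940 each), and the nerve call also without strained replicate 3 (0.130) or unstrained replicate 1 at 1 h (0.0539). Both were also lost without a filter on dim probes (0.133 each), the nerve call with the stricter filter (0.0943) or array weights (0.0545), and the smooth muscle call with only the groups compared (0.0595).

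Of the genes fixed in advance, Mmp13 and Mmp14 alone passed at 24 h. Col1a1 had a log2 fold change of 0.57 ± 0.84 (adjusted p = 0.898), Col3a1 of -0.53 ± 0.71, Dcn of -0.27 ± 0.09 (adjusted p = 0.201) and Tnmd of -0.37 ± 0.33. Mmp3, Timp1 and Timp3 stood at 0.11, 0.12 and 0.12, Il6 at -1.31 ± 0.67, Ptgs2 at 0.92 ± 0.29 (adjusted p = 0.140), Egr1 at 0.37 ± 0.41 and Fos at -0.12 ± 0.39. Timp1, Dcn and Mmp3 had mean signals over all arrays of 10662, 9498 and 8573. The highest value on every array was 14804, so a rise of these genes is capped at both times.

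**Figure D3:**
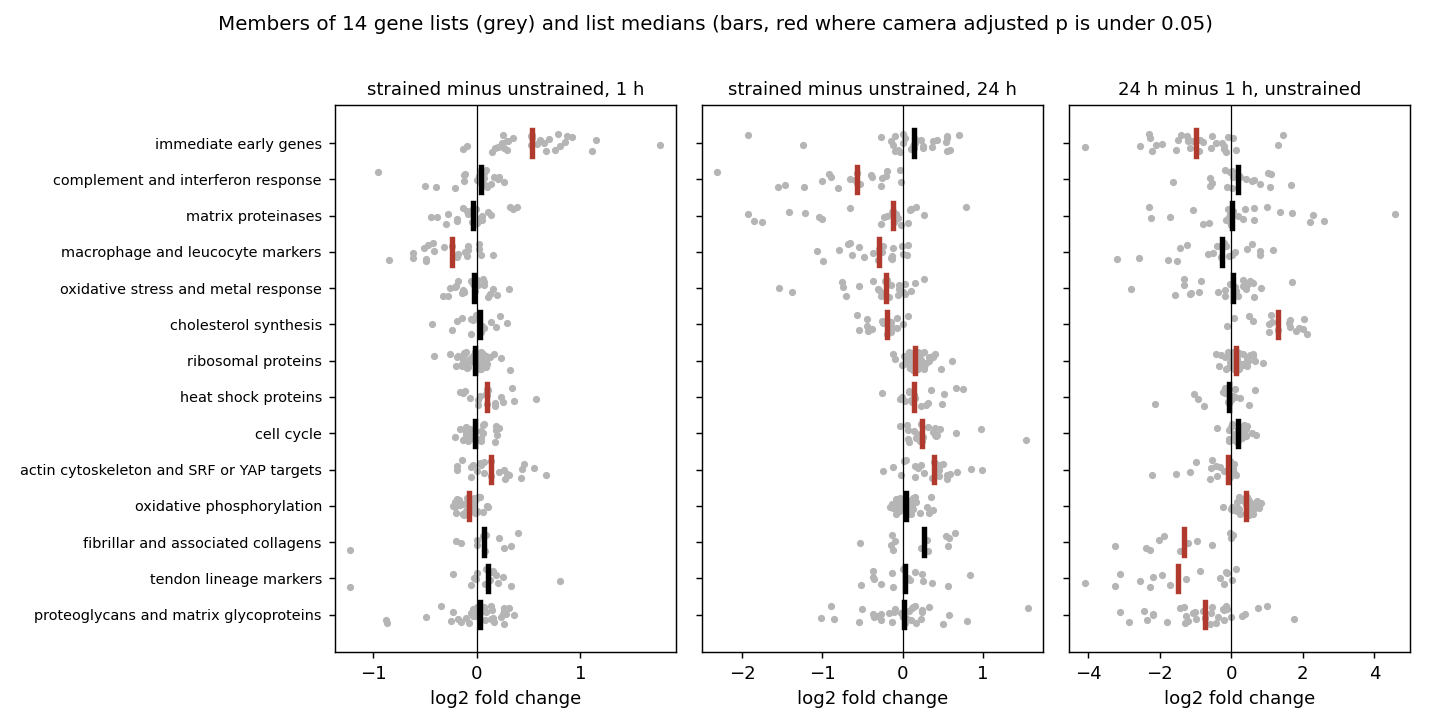
Log2 fold changes of the members of 14 gene lists (grey points) and each list's median (bars, red where camera's adjusted p with the preset correlation is under 0.05) for strain at 1 h, strain at 24 h, and time in unstrained fascicles. Horizontal axes differ between panels, and the vertical position of points within a list carries no value. The immediate early genes have a median of 0.53 at 1 h and the complement and interferon genes of -0.57 at 24 h.

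The 24 h count depended on single arrays. It was 69 without strained replicate 2, 95 without strained replicate 3, and 109, 118 and 107 without unstrained replicates 1, 2 and 3. Of the 39 genes named by the fixed rule and called at 24 h, 12 were called in every fit that left out an array, Orm1, Hp, Cyp4b1, Lbp, Serping1, Enpp2, Adamts5, Adamts1, Mmp13, Esm1, Ncl and Pmepa1. None of the 39 could change sign in these fits, since their strained and unstrained arrays did not overlap. With array weights, limma called 558 probes, all 263 among them.

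Without a block, the strain effect differed between the times for 9 probes, all with a lower effect at 24 h. These were tested by the difference of the effects itself. Orm1 led with a difference of -3.49 ± 0.21 (adjusted p = 8.16e-06), from 0.07 at 1 h to -3.42 at 24 h. Hp followed at -3.09 ± 0.19 and Cyp4b1 at -2.24 ± 0.20 (adjusted p = 4.47e-04), then Asgr1, a hepatic lectin gene, at -1.87 ± 0.24 and Nfil3, a transcription factor of the circadian clock, at -1.54 ± 0.20. The count was 16 without unstrained replicate 1 at 1 h, of which 4 had a higher effect at 24 h, and 15 without strained replicate 3 at 1 h, of which 1 had. With a variance trend and robust estimation it was 19, of which 2 had. With the replicate number as a block the counts were larger and went both ways, as given with the processing.

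By list, immediate early genes had a lower effect at 24 h, by a median of -0.41 (camera adjusted p = 1.68e-05; adjusted p = 0.387 with an estimated correlation), and 6 members were lower adjusted over the list alone. Atf3 (-1.21 ± 0.21), Gem (-1.77), Dusp1 (-0.82) and Fos (-1.89) led without passing over all probes. Complement and interferon response genes had a median difference of -0.61 (camera adjusted p = 2.35e-06; adjusted p = 0.308 with an estimated correlation), led by C2 (-1.33), Psmb9 (-0.65), Serping1 (-1.35) and C1s (-1.16). Matrix proteinases had 5 members lower adjusted over the list alone (camera adjusted p = 6.73e-04; adjusted p = 0.167 with an estimated correlation), with Adamts5 at -1.67, Mmp13 at -1.18, Adamts1 at -1.76 and Mmp14 at -1.52.

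No probe was called at both times, because none was called at 1 h. Across the 11258 probes the strain effects at 1 h and 24 h had a Pearson r of 0.147 and a Spearman rho of 0.117, and probes are not independent replicates. Of the 263 probes called at 24 h, 167 had the same sign at 1 h, which is 63.5%. These comparisons share no array. Hbegf stood at 1.11 at 1 h, where its adjusted p was 0.0464 with the block and 0.831 without it, and at 1.57 at 24 h.

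In unstrained fascicles, far more probes changed between 1 h and 24 h than changed with strain at either time. Among named genes, the largest rises were those of Slpi, by 6.03 ± 0.73 on the log2 scale, Lcn2 by 5.14 ± 0.81, Chi3l1 by 4.14 ± 0.79 and Orm1 by 4.13 ± 0.15, and the macrophage elastase Mmp12 by 4.58 ± 0.66. The largest falls were those of Egr1 at -4.10 ± 0.41, Col1a1 at -3.26 ± 0.84, Mfap5, a microfibril protein, at -3.12 ± 0.40, Myoc at -2.90 ± 0.73 and the macrophage gene C1qb at -3.18 ± 0.27. In all, 1942 probes were called, 1107 higher and 835 lower.

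Matrix and tendon genes were lower after 24 h without strain. Of 12 fibrillar and associated collagens 7 fell, among them Col15a1 (-2.39), Col6a1 (-1.89), Col14a1 (-2.27) and Col4a1 (-0.96), at a median of -1.31. Of 16 tendon lineage markers 9 fell and none rose, Egr1, Egr2, Loxl2 (-1.93) and Mfap5 foremost, at a median of -1.49. Egr1 and Egr2 are also immediate early genes, whose fall is given below, so these falls are not fully separate results. Of 34 proteoglycans and matrix glycoproteins 17 fell, among them Ecm1 (-2.35), Ogn (osteoglycin, -2.44) and Cspg4 (-1.20), and 1 rose, Emilin1 (1.77). Adjusted over the list alone the numbers that fell were 8, 10 and 20. Camera gave adjusted p of 9.57e-05, 3.61e-07 and 6.24e-07, and adjusted p = 0.210, 0.158 and 0.136 with an estimated correlation. The cartilage markers Chad (-2.86), Col11a2 (-1.43) and Hapln1 (-0.53) fell too, 3 of 10 measured, also adjusted over the list alone, and Sox6 stood at -0.22 (camera adjusted p = 0.0336; adjusted p = 0.282 with an estimated correlation).

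Of 17 cholesterol synthesis genes 15 rose, with Fdft1 4.01-fold higher and log2 fold changes of 2.03 for Sqle, 1.61 for Mvd and 1.65 for Idi1, a median of 1.29 for the list. Of 36 oxidative phosphorylation genes 18 rose, among them Cox7b (0.77), Ndufs1 (0.83), Ndufb5 (0.65) and Ndufb3 (0.76), and of 29 hypoxia and glycolysis genes 12 rose, among them Angptl4 (2.06), Ldha (1.13) and Eno1 (1.20), while 3 fell, among them Hk2 (-1.02). Adjusted over the list alone, 15, 23 and 15 rose. Camera gave adjusted p of 5.93e-13, 1.96e-08 and 5.22e-04, and adjusted p = 0.136, 0.164 and 0.310 with an estimated correlation. Ribosomal protein genes had 7 of 48 higher, with Rpl31 at 0.89, Rpl7 at 0.67, Rpl23 at 0.45 and Rps26 at 0.60 (camera adjusted p = 0.0133; adjusted p = 0.301 with an estimated correlation).

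Immediate early genes fell in 18 of 30 cases, with Egr2 at -2.54, Zfp36 at -2.30 and Myc at -2.28, and 2 rose, Gem and Rgs2, the latter with an adjusted p up to 0.164 with an array left out, without unstrained replicate 2 at 24 h (camera adjusted p = 2.74e-10; adjusted p = 0.136 with an estimated correlation). Of 34 genes of the unfolded protein response 11 fell, Herpud1 by 1.78, Creld2 by 1.09, Hspa5 by 0.87 and Aars1 by 0.70, and 1 rose (camera adjusted p = 2.26e-05; adjusted p = 0.164 with an estimated correlation). Glucocorticoid and circadian genes had 6 of 15 lower, with Errfi1 at -2.09, Klf9 at -1.73, Bhlhe40 at -1.64 and Sgk1 at -1.40 (camera adjusted p = 1.97e-04; adjusted p = 0.136 with an estimated correlation). Actin cytoskeleton genes and targets of SRF or YAP had 8 of 23 lower, with Ccn2 at -1.56, Ezr at -1.16, Tubb6 at -0.99 and Vim at -0.53 (camera adjusted p = 0.00144; adjusted p = 0.164 with an estimated correlation). Adjusted over the list alone, 19, 18, 8 and 9 were lower in these lists.

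The lists of signalling, adhesion and proteinase inhibitor genes went both ways. TGF-beta and BMP genes had 11 of 35 lower and 3 higher, with Ltbp4 at -1.39, Tgfb3 at -1.47 and Chrd at -0.79 against Ltbp2 at 2.89 (camera adjusted p = 0.00341). Integrin and focal adhesion genes had 9 of 26 lower and 2 higher, with Sdc1 at -0.96, Itgb5 at -0.91 and Itgb1 at -0.44 against Parva at 1.11 (camera adjusted p = 0.0108). Proteinase inhibitors had 5 of 11 lower and 2 higher, with Serpinf1 at -1.33, Cst3 at -1.30 and Timp3 at -0.61 against Tfpi at 0.70 (camera adjusted p = 0.0252). Adjusted over the list alone 13, 9 and 6 were lower, and all 3 lists had adjusted p = 0.136 with an estimated correlation.

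Any difference between array batches of the 2 times cannot be told apart from time in culture, since no array batch is given in the sources used here. The count was 1227 without unstrained replicate 1 at 24 h. Col1a1 lost its call without unstrained replicate 2 or 3 at 1 h or unstrained replicate 1 or 2 at 24 h (adjusted p = 0.0629, 0.0796, 0.0851 and 0.0512), and Myoc without unstrained replicate 1 or 2 of either time (0.0613, 0.0513, 0.0803 and 0.0694). Hapln1 lost its call without unstrained replicate 2 or 3 at 1 h or 1 or 2 at 24 h (0.0858, 0.0890, 0.0868 and 0.0739), and Vim without unstrained replicate 3 at 1 h or 2 at 24 h (0.0524 and 0.0515). The cartilage list lost its call without unstrained replicate 3 at 1 h (0.119) or 1 at 24 h (0.0544), the proteinase inhibitors without unstrained replicate 1 at 1 h (0.0877) and the ribosomal proteins without unstrained replicate 1 at 24 h (0.0534). With cyclic loess the cartilage and ribosomal lists lost their calls (0.0543 each), and without a filter on dim probes the proteinase inhibitors did (0.167, median -0.32).

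Of the 154 probes lower with strain, 82 were higher with time, against 15.1 for independent lists, and of the 109 higher with strain, 41 were lower with time, against 8.08. Of the 1107 probes higher with time, these 82 are a small part. Orm1, Hp, Lbp, Adamts5, Adamts1, Mmp13 and Mmp14 are of the first kind, and Hbegf, Tnfrsf12a, Ezr, Sdc1 and Il1rl1 of the second. Both contrasts use the same unstrained arrays at 24 h, which alone ties them in this direction. Called or not, 121 of the 154 (78.6%) and 65 of the 109 (59.6%) had the opposite sign with time. In 50 simulated refits with no change in any group, the shared arrays alone gave 66.7% over all probes. That share covers all probes, while the 154 and 109 were picked for their strain effect. It is thus no expectation for them, and the comparison cannot decide. The Pearson r across probes was -0.320, against -0.433 from shared arrays with no effect, and the covariance was -0.0385 against -0.0117. Part of the excess of 82 over 15.1 and of 41 over 8.08 may come from the shared controls. Their 3 arrays are too few to split into 2 sets of at least 2.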

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

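The comparisons of other splits for strain at 24 h, for the difference and for time, and the test of the shared arrays, were set before their results were seen, while the tests on macrophage markers, on pairs, on random lists and on the splits at 1 h were chosen only after.

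Strain had different effects at 1 h and 24 h on 9 probes by a test of the difference itself, in the fit without a block. The log2 differences were -3.49 for Orm1, -3.09 for Hp, -2.24 for Cyp4b1, -1.87 for Asgr1, -1.54 for Nfil3, -1.33 for Plpp3, -1.33 for Bst1, -1.10 for Rnf125 and -2.69 for the unnamed probe ILMN_1357368. Plpp3, Bst1 and Rnf125 each lost their call in some fit that left out an array, with adjusted p up to 0.0606 without unstrained replicate 1 at 24 h, 0.0670 without strained replicate 2 at 1 h and 0.108 without unstrained replicate 2 at 1 h. By the same contrast, 10 lists differed with the preset correlation and none with an estimated one. Their median differences were -0.61 for complement and interferon response, -0.41 for immediate early genes, 0.19 for ribosomal proteins, -0.10 for matrix proteinases, -0.29 for cholesterol synthesis, 0.23 for the cell cycle, 0.12 for oxidative phosphorylation, 0.26 for actin cytoskeleton genes, 0.32 for smooth muscle and pericyte markers and -0.20 for oxidative stress and metal response. The last 6, from cholesterol synthesis on, each lost their call in at least 2 of the 12 fits that left out an array. Without strained replicate 3 at 24 h the adjusted p was 0.603 for the cell cycle, 0.270 for oxidative phosphorylation, 0.138 for actin, 0.0598 for smooth muscle and 0.311 for oxidative stress, and without strained replicate 1 at 24 h it was 0.0976 for cholesterol synthesis.

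Of 100 splits drawn from the 200 that regroup the arrays within each time, 10 gave at least 9 probes, so chance cannot be excluded for this count, and the highest other gave 369. All 10 kept the real groups at 24 h, as did 12 of the 100 in all, and the highest count among those that did not was 1. The splits with many calls thus carry the 24 h strain effect against regrouped arrays at 1 h, a structure of the samples.

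For the other counts the splits are too few for a share under 0.05. At 24 h, the real groups gave 263 probes, as many as in 1 of 10 splits, and the highest other split gave 1. For time in unstrained fascicles, the real groups gave 1942, again 1 of 10 splits, and the highest other gave 0. At 1 h without the block, the real groups gave 0, which 10 of 10 splits reach, and the highest other gave 13. With the block at 1 h, the real groups gave 23, reached in 1 of the 4 splits that part all 3 pairs, and the highest other gave 0.

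Strain at 24 h ran against the change over time in unstrained fascicles, with a covariance of -0.0385, below the -0.0324 that was the lowest of 1000 draws in which residuals of whole arrays changed sign at random. Against an unstrained 24 h array not used to pick the probes, strain had medians of -0.51, -0.36 and -0.10 on the 200 strongest risers but of 0.18, 0.06 and -0.12 on the 200 strongest fallers, so the bound set in advance was not met and shared arrays stay open as a cause. A lower share of macrophages and leucocytes was first tested on all 21 markers. Their mean was -0.37 ± 0.07 (SE over markers), or -0.51 less 2 standard errors, above the median of -0.86 of the 154 probes that fell. This comparison cannot decide, since the markers were measured on the same arrays, with an estimated correlation of 0.50, and their standard error is too small. The 154 probes were also picked for their fall. After that outcome was seen, the test was narrowed to the 8 markers with a mean log2 level above 6.5 in unstrained fascicles, since changes near background are hidden, and their mean was -0.69 ± 0.09, or -0.863 less 2 standard errors, against -0.859. The outcome thus turns on a limit chosen afterwards and stays open, and 51 of the 154 probes fell further than Fcer1g (-1.07), the marker with the largest fall.

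Immediate early genes stood higher after 1 h of strain in each of the 3 pairs. The lowest pair's median over the list was 0.50, so the rise was not carried by a single pair. Random lists matched on mean signal reached a median of at most 0.13 in 10000 draws, against 0.53. The list thus lay beyond random genes of like signal. This cannot test a general shift of dim or bright probes, since normalization had already given all arrays the same sorted values. A response to strain stays open as a hypothesis, and a response to the handling that strained fascicles alone may have had was not tested.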

How the results depend on the processing

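Of 148 gene results and 42 list results called and run under the alternatives, 0 changed sign, with a gene or list counted once for each contrast. The arrays of the 2 groups did not overlap for any of the 263 probes called at 24 h. The same held for 1920 of the 1942 called with time. For these, leaving out an array could not change the sign. Genes not called did change sign, such as Col1a1 at 1 h (-0.58 to 1.00 with an array left out). However, the number of probes called moved. At 24 h the 263 became 558 with array weights, which hold all 263, and 73 with a minimum of 2-fold, and ranged from 69 to 307 with an array left out, where fewer arrays are tested. At 1 h the 0 became 1 with a variance trend and robust estimation (Atf3) and ranged from 0 to 2 with an array left out (Atf3 and Pi16 without unstrained replicate 1). The 9 probes of the difference became 19 with the trend and robust estimation (2 higher at 24 h) and 7 to 16 with an array left out. The 1942 of time became 416 with a minimum of 2-fold and 1227 to 2117 with an array left out. The overlap of 1 h and 24 h calls was 0 in every fit without a block within each time. The cause of the shifts with array weights and the trend was not tested.

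With the replicate number as a block within each time, 23 probes were called at 1 h, 882 at 24 h (all 263 among them), 184 for the difference (54 higher and 130 lower at 24 h) and 3 for the overlap with 1 direction, Rhob, Jun and Hbegf. As a block over all 12 arrays it gave 0 at 1 h, 30 for the difference (7 higher) and 378 at 24 h. With the block within time, the matrix proteinases at 24 h had an adjusted p of 0.322 with an estimated correlation, so that call is lost. By fry they kept it (0.0374), while actin, heat shock, ribosomal, complement, nerve and smooth muscle lists lost theirs (0.0536 to 0.0962). Oxidative stress (0.0374) and integrins (0.0436) passed fry only with the block. By camera it added cytokines at 24 h (0.0334) and for the difference (0.0228), and nerve markers for the difference (0.0401). At 24 h the deviations of replicates 1, 2 and 3 correlated at 0.0387, 0.309 and 0.388, and 5 of the 6 arrays correlated best with their own number, a hint from the data and not from the design. Beyond the calls given with the 1 h results, the block changed no other list call at 1 h.

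Cyclic loess, no filter, the stricter filter, fits on only the groups compared and normexp with offsets of 16 or 50, chosen after seeing the data, kept every count within 1.5 times. List calls were less steady. At 1 h, heat shock, actin, oxidative phosphorylation and unfolded protein lost theirs with normexp at offset 16 (adjusted p = 0.0685 to 0.0820) and with array weights, and oxidative phosphorylation with loess (0.0608) and unfolded protein without a filter (0.0566). The losses at 24 h and for time stand with those lists. For the difference, oxidative phosphorylation lost its call with loess (0.0992) and array weights (0.0562), the cell cycle with array weights (0.0629) and smooth muscle without a filter (0.197). Not run were an alternative without background correction and the table in place of raw signals, since both are the values used, a change of offset in a correction not applied, median scaling, since every array has the same median, a chip block, since chips are not given in the sources used here, the 2-group fit for the difference, and the block within time for the time contrast.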

Other observations

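Several further lists did not pass camera between 1 h and 24 h in unstrained fascicles, while single genes passed limma's adjusted p in both directions. Among them, growth factors and receptors had 5 of 22 higher and 5 lower (camera adjusted p = 0.243). Complement and interferon genes had 5 of 21 higher and 1 lower (camera adjusted p = 0.320). Genes are given here for 3 other such lists, and these lists and genes were chosen after their values were seen. Of 35 cytokine, chemokine and prostaglandin genes 8 rose and 2 fell, with Ccl20 at 3.79 and Nos2 at 2.13 against Il1rl1 at -2.19 and Ptgis at -1.26 (camera adjusted p = 0.530 for the list). Of 26 matrix proteinases 8 rose and 5 fell, so that the list's median was 0.02: Adamts5 rose by 2.60, Mmp10 by 2.28 and Adamts1 by 2.19, while Ctsk, the collagen-degrading cathepsin K, fell by 2.24 and Ctss by 1.72 (camera adjusted p = 0.258). Oxidative stress genes had 7 of 24 lower and 3 higher, with Hmox1 at -2.81, Gclc at -1.57 and Txnrd1 at -1.31 against Sod1 at 0.61 (camera adjusted p = 0.272).

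Macrophage and leucocyte genes parted over the same time. C1qb, C1qc and C1qa fell by 3.18, 2.59 and 1.76, and Aif1 by 1.53 and Laptm5 by 1.42, while Fcgr2b rose by 1.17 and Cd53 by 0.81, 6 lower and 3 higher in all (camera adjusted p = 0.0841). At 24 h Fcgr2b and Cd53, which had risen, were called lower with strain. Lower values were not confined to markers that had risen: 18 of 21 lay lower with strain, among them Aif1 (-0.99, not called), which had fallen. Both contrasts use the same unstrained arrays at 24 h.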
